A study of Homo sapiens with 18 samples.

How the data were processed

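RNA from NCI-H2347, an established human lung cancer line, was profiled on Illumina HumanHT-12 v4 BeadChips with 1 colour (biotin). Per the labels, the cells grew in RPMI medium with 5% fetal bovine serum and received, 24 h after plating, medium with 50 µM pioglitazone or the DMSO vehicle for 12, 24 or 48 h. There were 3 arrays for each of the 6 groups, 18 in all. Nothing in the sources used here says that the replicates of a group came from separate cultures.

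The unnormalised table held a signal intensity for each of 47323 probes on each array, exported by the authors from GenomeStudio per the submitters' processing notes; its version and settings are not given in the sources used here. These intensities were neither background-subtracted nor normalised between arrays, judging from their lowest values and medians. Beside each intensity the authors deposited a detection p-value, the share of negative-control probes at or above that signal, in steps of 1 in 770. A second table held the authors' processed values of the same arrays, which the authors deposited as linear intensities with the same set of values on every array (median 10.4, maximum 28864). These were quantile-normalised after a background correction whose method and tool are not given in the sources used here. Within each array they ranked the probes as the unnormalised table did.

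The unnormalised intensities were background-corrected and quantile-normalised with neqc in limma 3.58.1 (R 4.3.3), with negative-control values inferred from the detection p-values and an offset of 16, and were taken to log2. Probes were kept where the detection p-value was under 0.01 on at least 3 of the 18 arrays, which left 20032. Genes were named through a table of platform annotation that gave 1 symbol for 30113 probes, several for 8 and none for 17202. Of the named probes, 30074 had a gene in the NCBI RefSeq table of assembly GRCh38.p14, which changed 0 symbols, and 39 had none and kept the annotated symbol. Probes with several symbols were not named. The array files name no genome build, so no coordinates are given. Of the kept probes, 15678 had a symbol and 4354 had none. Each gene was represented by its kept probe of highest mean signal, which gave 11680 genes, and 3161 genes had more than 1 kept probe. Where another kept probe of a gene named in the text differed in direction or by more than 0.5 on the log2 scale, its value is given. A probe not detected on any array of a group has only a bound there, and the change is then also given as at least N-fold. For this bound the dim group was set, array by array, at the higher of its own signal and the lowest signal among probes above background.

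Each array detected between 17040 and 18880 probes, 36.0% to 39.9% of the total. The number of arrays limits the precision: the median standard error of a log2 fold change at 1 time was 0.15. Pearson correlations across genes were 0.973 to 0.995 between arrays of a group and 0.941 to 0.988 between arrays of different groups. No pair of arrays was identical.

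Pioglitazone was compared with vehicle at each time, the 3 effects were compared with each other, and vehicle at 24 h and at 48 h was compared with vehicle at 12 h. All comparisons came from 1 limma fit of group means over the 18 arrays (12 residual degrees of freedom) with empirical Bayes moderation. A gene passed the threshold at a Benjamini-Hochberg adjusted p-value under 0.05 over the 11680 genes. The 45 gene lists were fixed beforehand; 43 had at least 5 tested members. They were tested at each time with camera at a preset inter-gene correlation of 0.01, adjusted over the 129 tests, and again with an estimated correlation and with fry. camera sets the members of a list against all other genes, while fry asks only whether they move, on balance, one way. Counts of list members are given over all genes tested and adjusted over the list alone. The gene lists, the designs, the alternatives and the rule for named genes were all set before the data were examined, except where stated.

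The named genes were, at each time, the 8 highest and 8 lowest log2 fold changes past the threshold whose 3 treated values all lay on one side of the 3 vehicle values. Genes named in every case were PPARG, RXRA, PDK4, ANGPTL4, PLIN2, FABP4, CPT1A, CDKN1A and CCND1, and a further gene that is not reported here. In each list up to 4 members per direction past the threshold were named, or up to 2 where none passed. For each difference between times and each vehicle comparison, the 4 highest and 4 lowest were named.

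The fits were tested on simulated data with the real genes' means and spreads, in which 100 genes were changed 1.5-fold and 100 genes 2-fold. At 12, 24 and 48 h, 51, 56 and 49 of the 1.5-fold changes and 83, 93 and 93 of the 2-fold changes were recovered. For the differences between 12 and 24 h, 24 and 48 h, and 12 and 48 h, 21, 14 and 18 of the 1.5-fold and 55, 54 and 64 of the 2-fold changes were recovered. For vehicle at 24 h and at 48 h against 12 h these were 53 and 51, and 93 and 93. A planted list of 25 genes shifted by 0.40 on the log2 scale was called at each time, with 0 of 42 unshifted lists. Simulated genes varied independently and lists were drawn at random, so the preset correlation was not put to the test. The recovery rates hold only for this number of changed genes, and more genes passed in the data at 12, 24 and 48 h.

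The alternatives set beforehand were no background correction, median scaling in place of quantile normalisation, the authors' values, an offset of 50, no detection filter, detection on all arrays, the mean of a gene's probes, counting probes, limma-trend, array weights, the replicate number as a block, only the groups compared, at least 1.5-fold (for counts of genes), leaving out each array in turn, camera with an estimated correlation, and fry. A block for the chip could not be run, since the files name no chip. The background signal split the arrays into 2 classes, and this class as a block, and list tests on the differences between times and on the vehicle comparisons (the latter also with this block), were added after the data were seen. Symbols starting with LOC were counted and not named. Probes with no gene name were tested apart from the genes.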

Results

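The experiment followed the transcriptome of NCI-H2347, a line of lung cancer cells, exposed to 50 µM pioglitazone, a thiazolidinedione that activates the nuclear receptor PPARγ, or to the DMSO vehicle. It comprised 18 BeadChip arrays, 3 for each treatment at 12, 24 and 48 h, and 11680 genes had a probe that could be tested. Nothing says that the 3 replicates of a group were separate cultures, so the p-values measure only the spread between these samples, which may be technical. The arrays fell into classes of background signal, the median signal of undetected probes. It was 97.8 to 108 on 11 arrays, namely all arrays at 12 h, the vehicle arrays at 48 h and pioglitazone replicates 1 and 2 at 48 h. It was 130 to 145 on the other 7, which were all arrays at 24 h and pioglitazone replicate 3 at 48 h. The comparisons at 12 and 24 h therefore each lay within 1 class. At 48 h the comparison within the lower class is the one without the third pioglitazone array. The class as a block gives the same fold changes by construction, since no other group mixes the classes, and is no separate check.

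**Figure D1:**
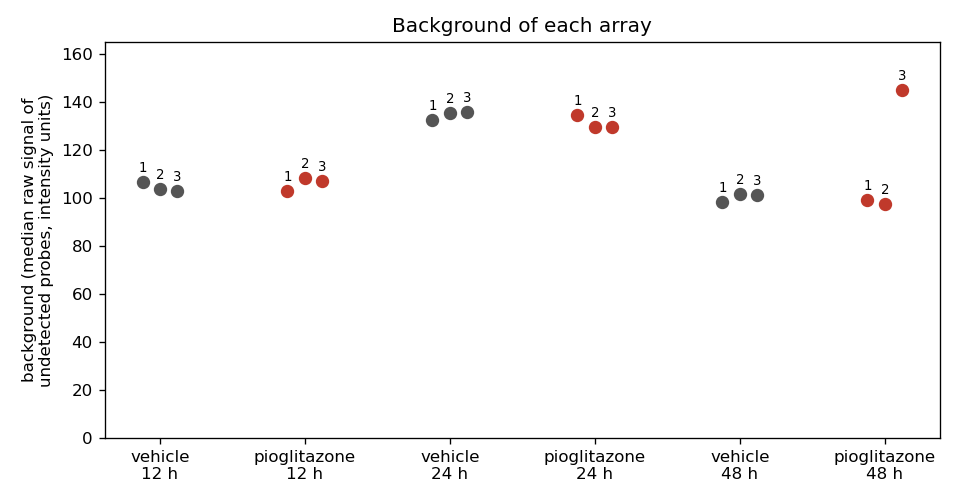
Background of each array, as the median raw signal of undetected probes in intensity units (y axis, from 0), for the 6 groups of 3 arrays (x axis); each point is 1 array, numbered by replicate. The 7 arrays at 130 to 145 are those at 24 h and pioglitazone replicate 3 at 48 h, and the other 11 lie at 97.8 to 108.

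The first comparison asked what pioglitazone changed within 12 h. The lists of PPAR targets, peroxisomal fatty acid oxidation and cholesterol synthesis were called higher, and those of DNA replication and of inflammation lower. The largest rise was that of PDK4, the kinase that shuts off pyruvate dehydrogenase and a classical PPAR target (log2 fold change 2.50, SE 0.21, n = 3 per group, limma adjusted p = 2.71e-06). PLIN2, which coats lipid droplets, rose by 1.89 (SE 0.10, limma adjusted p = 7.98e-09), a 3.72-fold change. Next came INSIG1 (1.85), which restrains sterol synthesis, IDI1 (1.57), MVD (1.39) and MSMO1 (1.30), enzymes of the cholesterol pathway, the histone gene H2BC5 (1.53) and TMEM140 (1.35). Other kept probes of MSMO1 gave 0.05 to 1.57. The largest falls were those of the adhesion receptor gene ADGRF1 (−1.57), the sulfotransferase gene CHST4 (−1.5) and CYP1B1 (−1.46), a cytochrome P450. They were followed by ICAM1 (−1.43), a leukocyte adhesion molecule, SERTAD4 (−1.27), the cell-cycle transcription factor E2F2 (−1.25), MCM10 (−1.24), which starts DNA replication forks, and the claudin gene CLDN11 (−1.23).

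Of 28 measured PPAR target genes, 8 rose, 3 fell and 17 did not pass at 12 h (10 and 3 adjusted over the list alone, median 0.17, limma camera adjusted p = 2.93e-05). RETSAT, a retinol saturase, rose by 1.16 and CPT1A, which carries fatty acids into mitochondria, by 0.97, although a second CPT1A probe, above background on 7 of 18 arrays, gave 0.03. TXNIP (−0.77), CIDEB (−0.72) and SLC27A2 (−0.56) fell. In the peroxisomal fatty acid oxidation list 3 of 17 rose (7 up and 1 down adjusted over the list alone, adjusted p = 0.00161), among them catalase, CAT (0.65), and ECH1 (0.63). Of the lipid droplet genes, 2 of 17 rose and 1 fell (4 and 1 adjusted over the list alone, adjusted p = 0.0167), with LPIN1 at 0.90. The mitochondrial fatty acid oxidation list was called higher with 2 of 20 up and 1 down (4 and 1 adjusted over the list alone, adjusted p = 0.0399), a call that gave adjusted p = 0.116 with an estimated correlation. Cholesterol synthesis moved most: 15 of 19 genes rose and 0 fell, also adjusted over the list alone, with a median of 1.00 (adjusted p = 1.20e-20). Fatty acid synthesis was called higher with 3 of 19 up and 2 down (6 and 3 adjusted over the list alone, adjusted p = 0.0228), but adjusted p = 0.306 with an estimated correlation. Its members ACSS2 (1.08, other probes 0.33 to 1.00), FASN (0.77) and SCD (0.70) rose, while SCD5 (−0.45) and ELOVL6 (−0.44) fell.

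Stress programmes also rose at 12 h. Their lists share members with other lists, so the calls are not independent. This holds for 13 of 24 listed NRF2 targets, 8 of 28 ATF4 targets and 6 of 24 p53 targets. SESN2, for example, is in the ATF4, p53 and superoxide lists. Of 18 targets of the antioxidant regulator NRF2, 9 rose and 0 fell (13 and 0 adjusted over the list alone, median 0.46, limma camera adjusted p = 1.08e-08), including the haem oxygenase HMOX1 (0.96) and SRXN1 (0.87). Of 25 ATF4 targets of the integrated stress response 8 rose and 0 fell (13 and 0 adjusted over the list alone, adjusted p = 1.44e-09), led by CHAC1 (0.94), SESN2 (0.88) and VLDLR (0.77). Of 22 p53 targets 6 rose and 0 fell (11 and 0 adjusted over the list alone, adjusted p = 7.69e-05), with TP53INP1 at 1.13. The hypoxia-induced list had 8 of 17 up and 0 down (9 and 0 adjusted over the list alone, median 0.43, adjusted p = 3.82e-06), with ANKRD37 at 1.14 and PFKFB4 at 0.98. Of 11 canonical histone genes 7 rose and 0 fell (8 and 1 adjusted over the list alone, median 0.68, but 0.24 with no background correction and 0.44 with an offset of 50, adjusted p = 3.46e-07), among them H2BC21 (1.20). Of 21 autophagy and lysosome genes 6 rose and 0 fell (6 and 1 adjusted over the list alone, adjusted p = 0.000232), with the cholesterol exporter NPC1 at 0.89. Glycolysis was called with 3 of 22 up (3 adjusted over the list alone), adjusted p = 0.0165, but adjusted p = 0.0567 with an estimated correlation. The same held for superoxide removal (4 of 12 up, also adjusted over the list alone, adjusted p = 0.0224, and adjusted p = 0.127 with an estimated correlation). Glutamine, serine and one-carbon metabolism had 2 of 15 up and 1 down (3 and 2 adjusted over the list alone, adjusted p = 0.0318, and adjusted p = 0.271 with an estimated correlation). Endoplasmic reticulum chaperones had 2 of 17 up (3 adjusted over the list alone, adjusted p = 0.0263, and adjusted p = 0.0557 with an estimated correlation).

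Genes of growth and inflammation fell at 12 h. Of 18 NF-kB and inflammatory cytokine genes 10 fell and 0 rose (14 and 0 adjusted over the list alone, median −0.52, limma camera adjusted p = 5.75e-13), with the chemokine genes CXCL8 at −1.09, CCL20 at −0.99 and CXCL1 at −0.98. Of 31 DNA replication genes 14 fell (18 adjusted over the list alone, median −0.41, adjusted p = 4.81e-11), and POLE2, a subunit of DNA polymerase epsilon, fell by 0.74. Of 25 genes of the G1 to S transition 8 fell (9 adjusted over the list alone, median −0.31, adjusted p = 1.96e-07), with the phosphatase gene CDC25A at −1.17. Of 38 mitosis genes 4 fell (4 adjusted over the list alone, median −0.20, adjusted p = 3.55e-05), and this call gave adjusted p = 0.273 with an estimated correlation. In these 3 lists 0 members rose. Of 26 ribosome biogenesis genes 4 fell and 0 rose (4 and 0 adjusted over the list alone, adjusted p = 9.71e-05), led by RRS1 (−0.64).

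By limma 1028 genes passed at 12 h, 505 up and 523 down, 473 of them changed at least 1.5-fold and 69 at least 2-fold. With median scaling, which centred each array on the median of all its probes, most of them undetected, only 23 passed at 12 h (19 up, 4 down). It moved the median of all genes to 0.11 at 12 h, −0.20 at 24 h and 0.26 at 48 h. With array weights 2527 passed at 12 h and with the background class as a block 1635. All arrays at 12 h are of 1 class, so the block left the fold changes there unchanged. It only took the third pioglitazone array at 48 h out of the shared spread. Leaving out 1 of the 6 arrays at 12 h left 588 to 775 genes. Single arrays, median scaling, array weights or a fit of the compared groups alone ended the calls of mitochondrial fatty acid oxidation, superoxide removal, one-carbon metabolism, fatty acid synthesis and the chaperones.

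The second comparison was made at 24 h, where more genes passed. PDK4 and PLIN2 again stood among the largest rises, and most DNA replication genes were now lower. PDK4 was 7.23-fold higher (log2 fold change 2.85, SE 0.21, n = 3 per group, limma adjusted p = 1.32e-07) and PLIN2 4.10-fold higher (2.04). Next came BLID (2.23), a gene for a small protein named for a BH3-like motif, the calcium-binding protein gene S100P (2.03), ANKRD37 (1.97), the Notch-modifying glycosyltransferase gene LFNG (1.96), INSIG1 (1.94) and the protease gene CAPN5 (1.91). S100P was not above background on any vehicle array, so that it was at least 3.08-fold higher. The strongest fall was that of MCM10 (−2.13; its other probe gave −1.29), followed by RRM2 (−1.89), a subunit of ribonucleotide reductase. The DNA repair exonuclease gene EXO1 (−1.80, other probe −1.24), the retinal dehydrogenase gene ALDH1A3 (−1.79), UHRF1 (−1.77), E2F2 (−1.76, at least 2.99-fold lower as it was not above background with pioglitazone), DTL (−1.76) and the flap endonuclease gene FEN1 (−1.67) came next.

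At 24 h, 13 of 28 PPAR targets rose and 3 fell (15 and 3 adjusted over the list alone, median 0.44, limma camera adjusted p = 1.62e-06). FABP3, a fatty acid carrier, rose by 1.57 and was not above background on any vehicle array (at least 2.44-fold higher), and CAT rose by 1.34. Peroxisomal fatty acid oxidation had 9 of 17 up (10 adjusted over the list alone, median 0.45, but 0.20 with no background correction and 0.22 with median scaling, adjusted p = 1.54e-06), with ECH1 at 1.00 and ACAA1 at 0.93. Its mitochondrial counterpart had 7 of 20 up and 2 down (7 and 3 adjusted over the list alone, adjusted p = 0.0202, and adjusted p = 0.0859 with an estimated correlation). In cholesterol synthesis 17 of 19 rose (17 adjusted over the list alone, median 1.20, adjusted p = 5.30e-20), with HMGCS1 at 1.86 and MVD at 1.80. In fatty acid synthesis 9 of 19 rose and 2 fell (11 and 3 adjusted over the list alone, adjusted p = 0.000424, and adjusted p = 0.116 with an estimated correlation), with the desaturase gene FADS2 at 1.5. Among 17 hypoxia-induced genes 12 rose (12 adjusted over the list alone, median 0.70, adjusted p = 1.54e-10), with the vasodilator peptide gene ADM at 1.39. In glycolysis 10 of 22 rose (13 adjusted over the list alone, median 0.30, adjusted p = 4.31e-06), with PFKFB4 at 1.83, the aldolase gene ALDOC at 1.79 and ENO2 at 1.32. Of the NRF2 targets 13 of 18 rose (13 adjusted over the list alone, median 0.63, adjusted p = 2.60e-09), led by the aldo-keto reductase genes AKR1C3 (1.66) and AKR1B10 (1.60). The glutathione and thioredoxin list had 9 of 34 up and 2 down (10 and 2 adjusted over the list alone, adjusted p = 0.0472, and adjusted p = 0.0866 with an estimated correlation). Superoxide removal had 5 of 12 up (5 adjusted over the list alone, adjusted p = 0.0107, and adjusted p = 0.0970 with an estimated correlation).

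Of the histone genes 8 of 11 rose and 1, H4C3 (−0.79), fell at 24 h, the same adjusted over the list alone (median 1.14, but 0.60 with no background correction, limma camera adjusted p = 8.75e-08), with H2AC18 at 1.65 (its other probe gave 0.89). In the autophagy and lysosome list 6 of 21 rose (6 adjusted over the list alone, adjusted p = 0.0134), with the sialidase gene NEU1 at 1.14. DNA replication had 26 of 31 genes down (27 adjusted over the list alone, median −0.87, adjusted p = 9.44e-18), with CDC45 at −1.61 and CHAF1A at −1.56. The G1 to S list had 16 of 25 down (17 adjusted over the list alone, median −0.52, adjusted p = 4.95e-09), with CDC25A at −1.58, although its other probe gave −0.27. Mitosis had 20 of 38 down (24 adjusted over the list alone, median −0.44, adjusted p = 2.16e-07), and adjusted p = 0.162 with an estimated correlation. In the NF-kB list 10 of 18 fell (12 adjusted over the list alone, median −0.49, adjusted p = 6.70e-07), with the cytokine gene IL1A at −1.39 and the cyclooxygenase gene PTGS2 at −1.38. In ribosome biogenesis 10 of 26 fell and 1, WDR74 (0.78), rose (13 and 1 adjusted over the list alone, median −0.33, adjusted p = 2.95e-05), with RRS1 at −1.01.

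By limma 2725 genes passed at 24 h, 1226 up and 1499 down, 1252 of them at least 1.5-fold and 232 at least 2-fold. Median scaling left 448 (112 up, 336 down) and array weights gave 5780. The glutathione call was lost without 1 of 2 arrays (vehicle or pioglitazone replicate 2), with the background class as a block and under 5 other settings, the estimated correlation among them, and the mitochondrial oxidation call with median scaling and with array weights.

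The third comparison was made at 48 h, where mitotic genes fell together. BUB1, a kinase of the spindle checkpoint, was 7.79-fold lower (log2 fold change −2.96, SE 0.23, n = 3 per group, limma adjusted p = 3.39e-08). NEK2 (−2.87), CENPF (−2.86), BIRC5 (−2.84; its other probe gave −1.43), DLGAP5 (−2.81), CDC20 (−2.78) and KIF2C (−2.78), genes of the spindle, kinetochore and anaphase, lay beside it, as did the cytidine deaminase gene APOBEC3B (−2.80). PDK4 was 8.46-fold higher (3.08, SE 0.21, limma adjusted p = 1.03e-08). It was followed by SDCBP2 (2.50, other probes 1.86 to 2.31), the cell adhesion gene CEACAM6 (2.34), PLIN2 (2.32), the enolase gene ENO2 (2.01), DYSF (1.97), LFNG (1.91) and AKR1B10 (1.88). The log2 signal of AKR1B10 in vehicle was 7.21 to 7.49 at 12 h and 4.99 to 5.62 at 48 h. With pioglitazone it was 7.65 to 8.11 at 12 h and 7.02 to 7.19 at 48 h, so vehicle fell further. Without the third pioglitazone array, the one with the higher background, BUB1 stood at −3.21, PDK4 at 2.78, CEACAM6 at 2.10 and PLIN2 at 2.35.

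Of 38 mitosis genes 37 fell at 48 h (37 adjusted over the list alone, median −2.38, limma camera adjusted p = 2.84e-44), and adjusted p = 0.00289 with an estimated correlation. The exception, named after its value was seen, was the proliferation marker gene MKI67 (−0.31, limma adjusted p = 0.196). The median without the third pioglitazone array was −2.34, and −1.56 with no background correction. DNA replication had 26 of 31 down (28 adjusted over the list alone, median −0.94, and −0.87 without that array, adjusted p = 5.08e-17), with FEN1 at −1.83 and CDC45 at −1.76. The G1 to S list had 17 of 25 down (20 adjusted over the list alone, median −0.91, and −0.78 without it, −0.40 with no background correction and −0.58 with an offset of 50, adjusted p = 5.71e-11), with CCNA2 at −2.20, RRM2 at −1.95 and the thymidine kinase gene TK1 at −1.86. In the NF-kB list 13 of 18 fell (14 adjusted over the list alone, median −0.54, and −0.56 without it, adjusted p = 0.000131), with the lipocalin gene LCN2 at −1.38. Its median was −0.27 with no background correction and −0.24 with median scaling. Ribosome biogenesis had 8 of 26 down (11 adjusted over the list alone, median −0.26 with or without it, but 0.02 with median scaling, where that of all genes was 0.26, adjusted p = 0.000487), led by NPM3 (−1.02) and NOP2 (−1.01).

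Among the lists that rose at 48 h, PPAR targets had 15 of 28 up and 2 down (15 and 3 adjusted over the list alone, median 0.50, and 0.34 without the third pioglitazone array; limma camera adjusted p = 7.69e-05). CAT (1.49) and RETSAT (1.36) stood behind PDK4 and PLIN2, and CIDEB (−1.02) fell. Peroxisomal oxidation had 9 of 17 up (9 adjusted over the list alone, median 0.53, and 0.61 without it, but 0.31 with no background correction, adjusted p = 1.50e-05), with PHYH at 1.05. Cholesterol synthesis had 16 of 19 up (17 adjusted over the list alone, median 0.98, and 1.01 without it, adjusted p = 5.63e-12), with IDI1 at 1.63 and LSS at 1.56 (other probes 1.03 to 1.20). Fatty acid synthesis had 11 of 19 up and 1 down (14 and 3 adjusted over the list alone, median 0.35, and 0.32 without it, adjusted p = 0.00109, and adjusted p = 0.144 with an estimated correlation). Hypoxia-induced genes had 13 of 17 up (13 adjusted over the list alone, median 1.01, and 0.83 without it, adjusted p = 5.07e-12), with ADM at 1.72 and the mitophagy receptor gene BNIP3L at 1.61. Glycolysis had 16 of 22 up and 1, PFKM (−0.68), down (16 and 1 adjusted over the list alone, median 0.54, and 0.50 without it, adjusted p = 7.38e-08), with ALDOA at 1.24, where other probes gave 0.37 to 1.35. NRF2 targets had 14 of 18 up (14 adjusted over the list alone, median 0.84, and 0.73 without it, adjusted p = 6.39e-10), with HMOX1 at 1.51. The glutathione and thioredoxin list had 12 of 34 up and 2 down (12 and 3 adjusted over the list alone, median 0.19, and 0.15 without it, adjusted p = 0.0202), with GCLC, the enzyme that limits glutathione synthesis, at 1.28 and TXNRD1 at 1.03. Superoxide removal had 6 of 12 up (6 adjusted over the list alone, median 0.34, and 0.27 without it, adjusted p = 0.00520, and adjusted p = 0.0740 with an estimated correlation). Histone genes had 10 of 11 up and H4C3 (−1.18) down, the same adjusted over the list alone (median 1.18, and 1.24 without it, but 0.75 with no background correction, adjusted p = 2.27e-07). Epithelial junction and keratin genes had 8 of 21 up and 1 down (8 and 1 adjusted over the list alone, median 0.23, and 0.27 without it, adjusted p = 0.0224, and adjusted p = 0.114 with an estimated correlation), with the desmosome genes DSC2 at 1.00 and DSP at 0.74 and E-cadherin, CDH1, at 0.71.

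By limma 3469 genes passed at 48 h, 1669 up and 1800 down, 1738 of them at least 1.5-fold and 492 at least 2-fold. Within the lower background class 3305 passed (1484 up, 1821 down), of which 2748 were among the 3469, while median scaling left 554 (341 up, 213 down) and a fit of the 2 groups alone 1521. The epithelial call was lost without the first pioglitazone array. With no background correction the medians of 18 of the 54 called lists over the 3 times were smaller by more than 1.5 times.

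The receptor and its named targets varied. PPARG itself was at −0.26 at 12 h (limma adjusted p = 0.0984) and fell by 0.34 at 24 h (limma adjusted p = 0.0154) and by 0.39 at 48 h (limma adjusted p = 0.00502; −0.33 without the third pioglitazone array). Its other probe gave −0.09, −0.26 and −0.08, and its call was lost with median scaling at both times. RXRA, its dimer partner, stood at −0.17, −0.22 and 0.05 and did not pass at any time. ANGPTL4, a lipase inhibitor gene, stood at 0.17 and 0.39 and rose by 0.67 at 48 h (limma adjusted p = 0.0421), a call lost under 7 settings; its other probe, above background on 3 of 18 arrays, gave 0.88, 0.48 and 0.35, which are not exact changes. CPT1A rose at every time (0.97, 0.99 and 0.90), its second probe, mostly at background, gave 0.03, −0.22 and 0.38, and its call was lost with median scaling at 12 and 24 h. The cell-cycle inhibitor gene CDKN1A stood at 0.29, 0.32 and 0.02 and passed only at 24 h (limma adjusted p = 0.0440), a call that leaving out any of the 6 arrays at 24 h ended. Its other probe, above background on 3 of 18 arrays, gave 0.35, −0.25 and −0.26. Cyclin D1, CCND1, stood at −0.23, −0.08 and −0.30 and passed only at 48 h (limma adjusted p = 0.0230), a call lost within the lower background class (−0.26). FABP4 was not detected on enough arrays to be tested.

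**Figure D2:**
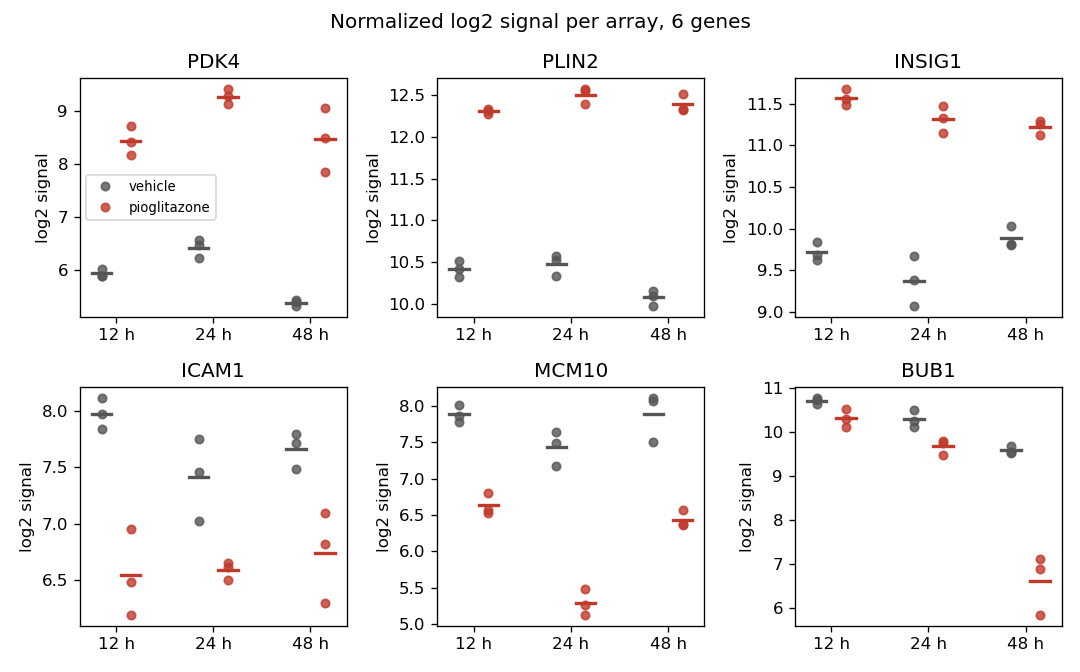
Log2 signal (y axis) of PDK4, PLIN2, INSIG1, ICAM1, MCM10 and BUB1 on each of the 18 arrays, by time (x axis) and treatment; points are arrays and bars are means of 3. PDK4 lay above its vehicle values on all 3 treated arrays at each time, and BUB1 averaged 6.62 with pioglitazone against 9.58 with vehicle at 48 h.

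**Figure D3:**
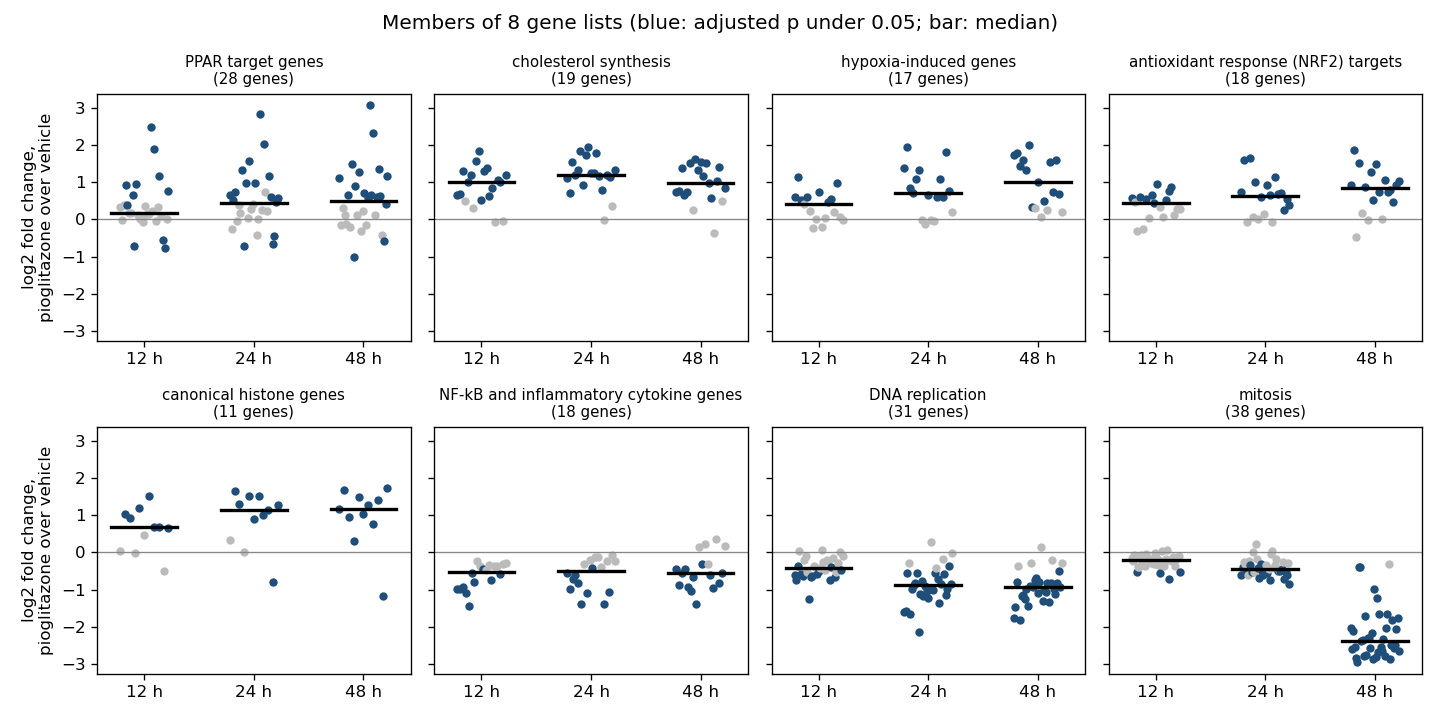
Log2 fold change of pioglitazone over vehicle (y axis) at 12, 24 and 48 h (x axis) for each measured member of 8 gene lists; blue points passed a limma adjusted p of 0.05, grey points did not, and bars are medians. The mitosis medians are −0.20, −0.44 and −2.38, and those of cholesterol synthesis 1.00, 1.20 and 0.98.

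Comparing the times asked which responses were early, late or lasting. Of all genes, 483 passed at every time, 225 higher throughout, 247 lower throughout and 11 in both directions. Between 12 and 24 h, 315 genes were higher and 346 lower at both, where independent lists would share 53 and 67.1. Between 24 and 48 h, 683 were higher and 827 lower at both (175 and 231 for independent lists), and between 12 and 48 h, 278 and 275 (72.2 and 80.6).

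The limma test of the difference passed for 81 genes between 12 and 24 h (41 up, 40 down), 398 between 24 and 48 h (146 up, 252 down) and 1063 between 12 and 48 h (453 up, 610 down). Leaving out 1 of the 12 arrays compared gave 30 to 199, 226 to 697 and 763 to 1295, and 7, 8 and 3 of 100 splits of the labels, the real one included, gave as many. From 12 to 24 h the response rose for BLID (1.76, SE 0.37), the lipid carrier gene FABP3 (1.55), CEACAM6 (1.49) and the defensin gene DEFB103A (1.40). It fell for the interleukin-33 receptor gene IL1RL1 (−1.78, SE 0.20, limma adjusted p = 0.000547), INHBE (−1.47), the stress cytokine gene GDF15 (−1.45) and HSPA13 (−1.43). From 24 to 48 h the response fell for the mitotic genes KIF20A (−2.70, SE 0.20, limma adjusted p = 3.46e-07), CDCA3 (−2.57) and KIF14 (−2.51) and for APOBEC3B (−2.58), and rose for EPB41L3 (1.61), CPSF6 (1.45), VGLL3 (1.31) and the kinase gene PLK2 (1.24). CPSF6 was above background on 1 of the 6 arrays at 48 h, and FABP3 and DEFB103A on none of the vehicle arrays at 24 h. From 12 to 48 h it rose for ERP27 (1.99), CEACAM6 (1.98), SDCBP2 (1.88) and LIMCH1 (1.84) and fell for DLGAP5 (−2.69), NEK2 (−2.66), KIF2C (−2.60) and KIF14 (−2.59).

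List tests on these differences, added after the data were seen, called 16 of 43 lists from 12 to 24 h, 4 from 24 to 48 h and 12 from 12 to 48 h, of which 5, 1 and 4 held with an estimated correlation. The mitosis response fell between 24 and 48 h (median of the difference −1.90, limma camera adjusted p = 9.49e-63, and adjusted p = 0.00531 with an estimated correlation). The hypoxia response grew from 12 to 24 h (0.32, adjusted p = 3.75e-07, and adjusted p = 0.010 with an estimated correlation), as did glycolysis (0.21, adjusted p = 0.000280, and adjusted p = 0.0221 with an estimated correlation). Peroxisomal oxidation did so too (0.33, adjusted p = 0.00108, and adjusted p = 0.0268 with an estimated correlation). The effects on ATF4 targets (−0.37, adjusted p = 2.31e-08, and adjusted p = 0.0103 with an estimated correlation) and endoplasmic reticulum chaperones (−0.38, adjusted p = 0.000100, and adjusted p = 0.010 with an estimated correlation) were lower at 24 h than at 12 h. The mean effect on ATF4 targets went from 0.35 to −0.02. That on the chaperones changed sign, from 0.16 to −0.20, and was not called at 24 h. In vehicle over this span ATF4 targets had 10 up and 1 down (median 0.19, adjusted p = 0.0515), and with the background class as a block they were called higher (median 0.18, adjusted p = 0.00917, and adjusted p = 0.407 with an estimated correlation). The chaperones had 8 up and 1 down in vehicle (median 0.35, adjusted p = 0.325), and with the block 4 up and 0 down (median 0.06, adjusted p = 0.0976). The DNA replication response deepened from 12 to 24 h (−0.47, adjusted p = 7.50e-10), but with adjusted p = 0.112 with an estimated correlation. The same held for mitosis from 12 to 24 h (−0.21, adjusted p = 0.0286, and adjusted p = 0.670 with an estimated correlation). One-carbon metabolism went from a mean effect of 0.13 at 12 h to −0.22 at 24 h. Its difference was called as well (−0.37, adjusted p = 3.08e-05), but with adjusted p = 0.0827 with an estimated correlation. From 12 to 48 h the mitosis response fell (−2.15, adjusted p = 7.97e-56, and adjusted p = 0.00531 with an estimated correlation), and those of hypoxia (0.62, adjusted p = 7.37e-09, and adjusted p = 0.00643 with an estimated correlation) and glycolysis (0.47, adjusted p = 2.42e-05, and adjusted p = 0.010 with an estimated correlation) rose. The chaperones fell over the same span (−0.28, adjusted p = 0.00366, and adjusted p = 0.0351 with an estimated correlation). ATF4 targets fell too (−0.33, adjusted p = 0.000100), but with adjusted p = 0.0644 with an estimated correlation. The NRF2 effect was larger at 48 h (0.37, adjusted p = 0.000211), but with adjusted p = 0.0827 with an estimated correlation. In vehicle over this span NRF2 targets fell (median −0.35, adjusted p = 0.0102, and adjusted p = 0.313 with an estimated correlation). Their mean effect was 0.39 at 12 h and 0.78 at 48 h, and their mean vehicle change −0.39, so the gain matched a fall in vehicle.

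The effects at 12 and 24 h were each measured within a background class, but that at 48 h, in the other differences, includes the third pioglitazone array of the higher class. With median scaling, which moved the medians of all genes to −0.32, 0.46 and 0.15, only 0, 11 and 67 genes passed for the 3 differences, and with the background class as a block 368, 406 and 1295. Between 12 and 24 h that block only takes the third pioglitazone array at 48 h out of the shared spread.

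The vehicle arrays alone showed how the untreated cultures changed with time. From 12 to 24 h the clock gene CIART (2.01, SE 0.15, limma adjusted p = 3.86e-07), the lysosomal membrane gene LAMP3 (2.0; its other probe gave 0.73), PHLDB2 (1.77, other probe 1.11) and SPRR2D (1.73) rose, and TNFRSF1B (−1.95), the replication licensing gene CDT1 (−1.86), CD247 (−1.85) and NBR1 (−1.84) fell. From 12 to 48 h ANKRD29 (2.06), LAMP3 (1.79, other probe 1.26), PRPH (1.75) and MAP1LC3A (1.69) rose. MCTP1 (−2.33, SE 0.14, limma adjusted p = 5.54e-08), the telomerase RNA gene TERC (−2.33, at least 3.83-fold lower as it was not above background at 48 h), AKR1B10 (−2.17) and RAB7B (−2.08) fell. The mitosis list fell in vehicle by 48 h (36 of 38 genes, median −1.0; limma camera adjusted p = 1.53e-25, and adjusted p = 0.101 with an estimated correlation). DNA replication fell by 24 h (24 of 31 genes, median −0.53, adjusted p = 4.50e-11, and adjusted p = 0.240 with an estimated correlation), as did the G1 to S list (20 of 25 down and 1 up, median −0.62, adjusted p = 1.95e-08, and adjusted p = 0.101 with an estimated correlation). Mitosis was lower by 24 h as well (25 of 38 genes, median −0.53, adjusted p = 4.50e-11, and adjusted p = 0.313 with an estimated correlation). With the background class as a block these 24 h medians were −0.51 for DNA replication (adjusted p = 1.96e-07), −0.55 for G1 to S (adjusted p = 3.37e-05) and −0.64 for mitosis (adjusted p = 6.31e-11), with only 3, 3 and 6 genes down, and 0 of the 5 lists then called at 24 h held with an estimated correlation (adjusted p = 0.407, 0.349 and 0.407 for these lists). At 48 h in vehicle DNA replication had 10 of 31 genes down (median −0.28, adjusted p = 0.00799, and adjusted p = 0.717 with an estimated correlation). The G1 to S list had 11 of 25 down there (median −0.45, adjusted p = 0.00247, and adjusted p = 0.313 with an estimated correlation). Heat shock proteins were lower at 24 h (median −0.20, adjusted p = 0.0291, and adjusted p = 0.614 with an estimated correlation). The glutathione and thioredoxin list was lower in vehicle at 48 h (3 of 34 up and 11 down, median −0.19, adjusted p = 0.0291, and adjusted p = 0.240 with an estimated correlation). NRF2 targets were lower in vehicle at 48 h (3 of 18 up and 9 down, median −0.35, adjusted p = 0.0102, and adjusted p = 0.313 with an estimated correlation), and so were NF-kB genes (1 of 18 up and 8 down, median −0.34, adjusted p = 0.00259, and adjusted p = 0.313 with an estimated correlation).

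By limma 4275 genes passed at 24 h (2351 up, 1924 down) and 2983 at 48 h (1399 up, 1584 down) against 12 h. The vehicle arrays at 24 h are all of the higher background class and those at 12 h of the lower, so with the class as a block, which rests on the third pioglitazone array at 48 h alone, 516 passed at 24 h and the calls of PHLDB2, TNFRSF1B, CDT1 and NBR1 were lost. Median scaling, which moved the medians of all genes to 0.54 at 24 h and −0.20 at 48 h, gave 3847 at 24 h (3695 up, 152 down) and 373 at 48 h (42 up, 331 down).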

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

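Of the tests in this part, the correlation that places the third pioglitazone array at 48 h and the hypoxia value at 12 h were chosen after the result was seen.

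The test of the difference between times passed for 81 genes between 12 and 24 h, 398 between 24 and 48 h and 1063 between 12 and 48 h. Leaving out 1 of the 12 arrays compared gave 30 to 199, 226 to 697 and 763 to 1295. Of 100 splits of the labels, the real one included, 7, 8 and 3 gave as many. A split can leave or invert the treatment effect of a time, so these shares do not show whether chance gives such counts. Between 12 and 24 h the differences with the largest changes were those of BLID (1.76), FABP3 (1.55), CEACAM6 (1.49) and DEFB103A (1.40), and of IL1RL1 (−1.78), INHBE (−1.47), GDF15 (−1.45) and HSPA13 (−1.43). All 8 lost their call with median scaling, BLID under 13 alternatives in all, GDF15 under 4 and DEFB103A under 3. Between 24 and 48 h they were EPB41L3 (1.61), CPSF6 (1.45), VGLL3 (1.31) and PLK2 (1.24), and KIF20A (−2.70), APOBEC3B (−2.58), CDCA3 (−2.57) and KIF14 (−2.51). The call of PLK2 was lost under 15 alternatives. Between 12 and 48 h they were ERP27 (1.99), CEACAM6 (1.98), SDCBP2 (1.88) and LIMCH1 (1.84), and DLGAP5 (−2.69), NEK2 (−2.66), KIF2C (−2.60) and KIF14 (−2.59). CPSF6 was mostly at background at 48 h, and FABP3 and DEFB103A were not above background on any vehicle array at 24 h, so their differences are not exact.

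Probes with no gene name, which the comparisons of genes leave out, also changed. Of 4354 such probes, 78 passed at 12 h (48 higher, 30 lower; 1.81 to −1.18), 431 at 24 h (274 higher, 157 lower; 1.87 to −1.43) and 508 at 48 h (265 higher, 243 lower; 2.17 to −2.78).

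The third pioglitazone array at 48 h shared its background with the arrays at 24 h. Across genes, its deviation from the other 2 arrays of its group correlated with the vehicle contrast of 24 h against the other times (r = 0.689), while the other 11 arrays at 12 and 48 h gave −0.206 to 0.249. Genes are not independent replicates, so this r has no p-value. A 24 h sample under a 48 h label is argued against: its mitosis median of 6.85 lay −32.7 SD from the mean of 9.18 of the pioglitazone arrays at 24 h (SD 0.0714), and the other pioglitazone arrays at 48 h had a mean of 6.68. A batch shared with the 24 h arrays is consistent with these values, and no biological explanation was tested for a single array.

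The mitosis list fell far more at 48 h than at 24 h. Without the third pioglitazone array the difference of the medians was −1.91, which argues against a shift brought by that array. All arrays left at 48 h are then of the lower background class and all at 24 h of the higher. Whether the class alters the size of a change therefore cannot be told apart from time. Over the 4 other scalings the difference of the medians ran from −2.19 to −1.18, which argues against the normalization. A rise in vehicle alone is argued against as well, since pioglitazone at 48 h lay −3.11 from pioglitazone at 12 h on the arrays of lower background, and vehicle fell by 1.00. A late loss of dividing cells under pioglitazone is a hypothesis that was not tested, since cell counts or cycle phases were not used here.

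The hypoxia-induced list rose with pioglitazone at each time. In vehicle the list changed by a median of 0.026 from 12 to 48 h, so time in culture alone did not raise it there. Whether treated and vehicle cultures differed in density cannot be told from this value, and density was not used here. The batch is argued against by the median of 0.43 at 12 h, where all 6 arrays share the lower background. Members shared with other lists are argued against by the median of 1.17 at 48 h over the 12 genes of no other list. The list test called it higher with pioglitazone at each time, also with an estimated correlation. Through what step the drug might act on this programme was not tested, and oxygen levels were not used here.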

How the results depend on the processing

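The background class as a block was chosen after seeing the data, and every other alternative in this part was planned. Direction was compared only where the main or the alternative value passed. A value that passed in neither counts as kept, whatever its sign. Of 2577 values for the gene lists at each time under an alternative, 2480 kept their side of the threshold, 38 weakened, 59 came past it and 0 reversed. Of 10681 for the named genes 9526 kept their side, 1127 weakened, 26 came past it and 2 reversed: PHLDA1 at 24 h with the mean of probes (0.076, its other probe 0.75) and CS at 48 h with median scaling (0.037, other probes −0.16 to 0.35). Median scaling centred each array on the median of all 47323 probes. Only 36.0% to 39.9% of these were detected per array, so that median lay among undetected probes. Median scaling weakened 359 of 581 named genes, and the cause was not tested. It left 23 genes at 12 h (82.6% up, against 49.1%), 448 at 24 h (25% against 45.0%) and 554 at 48 h (61.6% against 48.1%). For the differences it left 0 between 12 and 24 h, 11 between 24 and 48 h and 67 between 12 and 48 h. In vehicle it left 3847 at 24 h (96.0% up, against 55.0%) and 373 at 48 h (11.3% against 46.9%). Array weights, whose estimation stopped before it converged, gave 2527 at 12 h, 5780 at 24 h and 1968, 1167 and 1697 for the differences. The background class as a block gave 1635 at 12 h, 368 for the difference between 12 and 24 h and 516 for vehicle at 24 h. For the first 2 of these counts the block leaves the fold changes as they were. It only takes the third pioglitazone array at 48 h out of the shared spread. Fits of the compared groups alone gave 1521 at 48 h and 353, 179 and 690 for the differences. No background correction gave 204 and an offset of 50 gave 146 between 12 and 24 h. Of the medians of the 54 called lists, 18 were smaller by more than 1.5 times with no background correction, while median scaling made 12 smaller and 19 larger and turned 1, ribosome biogenesis at 48 h (0.02). Asking for 1.5-fold, which by construction keeps fewer, left 473, 1252 and 1738 at the 3 times and 2014 and 1373 in vehicle. By fry 85 list tests passed, against 54. The cause of the other moves was not tested. The replicate number as a block gave 940, 2640, 3375, 84, 337, 1025, 4191 and 2875 genes and 54 lists. The numbers do not pair the arrays: the deviations of the 9 same-numbered pairs correlated at −0.257 to 0.0910, and 2 fitted best with their own number. A block for the chip was not run, since the files name no chip.

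For the counts of genes, only arrays of the groups compared were left out, although all 18 arrays share the spread. Leaving out 1 array gave 588 to 775 genes at 12 h: 623, 612 and 592 without vehicle replicates 1, 2 and 3, and 588 and 656 without pioglitazone replicates 1 and 2. Between 12 and 24 h it gave 30 to 199. Without vehicle replicates 1, 2 and 3 at 12 h these were 35, 38 and 37, and at 24 h 45, 46 and 42. Without pioglitazone replicates 1 and 2 at 12 h they were 39 and 34, and without replicates 1, 2 and 3 at 24 h 199, 31 and 30. Between 24 and 48 h it gave 226 to 697. Without vehicle replicates 1, 2 and 3 at 24 h these were 249, 231 and 226, and without pioglitazone replicates 2 and 3 there 235 and 233. Without vehicle replicates 1 and 3 at 48 h they were 234 and 256, and without pioglitazone replicate 2 there 697. The other counts stayed within 1.5 times: 1859 to 2512 at 24 h, 2760 to 3655 at 48 h, 763 to 1295 between 12 and 48 h, 3215 to 3517 and 2099 to 2526 in vehicle, and 53 to 57 lists. Signal near background compresses changes, so a gene not above background in a group has only a bound there.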

Other observations

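The list tests on differences named in this part were chosen after the data were seen.

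By limma camera the respiratory chain list was not called (66 genes; medians −0.08, 0.04 and 0.01 at 12, 24 and 48 h, adjusted p = 0.0953, 0.267 and 0.973), with 0 genes past the threshold at 12 h, 5 up and 4 down at 24 h and 3 up and 7 down at 48 h. The tricarboxylic acid cycle was not called either (18 genes, adjusted p = 0.563, 0.267 and 0.480), although IDH1, which makes cytosolic NADPH, rose by 0.71 at 12 h. The pyruvate dehydrogenase list (12 genes, adjusted p = 0.0663, 0.181 and 0.507) held 2, 3 and 2 genes up, and PDP1, the phosphatase that opposes the PDK kinases, fell by 0.77 at 24 h. The pentose phosphate list had 1 up and 1 down, 3 and 2, and 4 and 3 of 8 (adjusted p = 0.688, 0.691 and 0.511), with PGD at 0.54, 1.15 and 1.07 and PRPS1 at −0.45, −0.53 and −0.81. Mitochondrial fatty acid oxidation at 48 h (adjusted p = 0.339), lipid droplets at 24 and 48 h (adjusted p = 0.0746 and 0.276) and one-carbon metabolism at 24 and 48 h (adjusted p = 0.0528 and 0.462) were not called. Targets of the liver X receptor were not called (9 genes, adjusted p = 0.688, 0.0685 and 0.573), but LPCAT3 rose at each time (0.79, 1.05 and 1.12) and the exporter gene ABCG1 fell (−0.53, −1.02 and −0.83).

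Some stress programmes called at 12 h were not called later. The p53 targets had 7 up and 4 down at 24 h and 7 up and 5 down at 48 h (adjusted p = 0.335 and 0.338), with PHLDA3 at 1.10 and 1.37 and GDF15 at −1.12 and −1.93. Their change between 12 and 24 h was not called (adjusted p = 0.131). The ATF4 targets had 2 up and 3 down, then 5 and 5 (adjusted p = 0.899 and 1.00), and the chaperones 0 and 4, then 1 and 6 (adjusted p = 0.0777 and 0.164). Autophagy and lysosome genes at 48 h (6 up, 3 down, adjusted p = 0.276), the glutathione list at 12 h (5 up, 1 down, adjusted p = 0.173) and the epithelial list at 12 and 24 h (adjusted p = 0.795 and 0.103) were not called. Heat shock proteins were not called (13 genes, adjusted p = 0.693, 0.658 and 0.694). Cell-cycle inhibitors and the RB family (10 genes, adjusted p = 0.973, 0.642 and 0.655) and regulators of apoptosis (18 genes, adjusted p = 1.00, 0.994 and 0.361) were not called, although BMF, a promoter of cell death, fell by 1.00 at 12 h and was at least 1.72-fold lower (its other probe gave −1.28).

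Lineage and signalling lists held changes in both directions. Lung lineage genes had 2, 4 and 7 up and 2, 4 and 6 down of 18 (adjusted p = 0.846, 0.590 and 0.964): the transcription factor gene CEBPA rose (0.79, 1.15 and 1.04), while the surfactant gene SFTPA1 fell at 24 and 48 h (−0.77 and −1.17). At 48 h MUC1 stood at 1.48 (other probes 2.04 to 2.76) and LAMP3, which rose in vehicle, at −1.79 (other probe −1.25). Interferon-stimulated genes (29 genes, adjusted p = 0.510, 0.440 and 0.151) had 8 down and 1 up at 48 h. Immediate early genes (20 genes, adjusted p = 0.869, 0.102 and 0.221) had 8 down and 2 up at 24 h. Targets of transforming growth factor beta (18 genes, adjusted p = 0.846, 0.494 and 0.573) and mesenchymal genes (14 genes, adjusted p = 0.361, 0.964 and 0.994) were not called. Nor were adipocyte markers (7 genes, adjusted p = 0.354, 0.494 and 0.691), xenobiotic metabolism (7 genes, adjusted p = 0.221, 0.869 and 0.837), nuclear receptors (13 genes, adjusted p = 0.562, 0.361 and 0.653) and metallothioneins (7 genes, adjusted p = 0.648, 0.834 and 0.170). Cytosolic ribosomal proteins stayed near the middle of all genes (42 genes; medians 0.00, 0.01 and −0.01, adjusted p = 0.901, 0.713 and 0.869). Housekeeping genes were not called (12 genes, adjusted p = 0.901, 0.724 and 0.335), but GAPDH rose by 0.53 (other probes gave 0.84 to 0.92) and GUSB fell by 0.81 at 48 h. Leukocyte markers were tested for 5 genes and 0 passed at any time (limma, adjusted p = 0.846, 0.939 and 0.546 for the list). Of 11 fibroblast markers COL1A1 and COL1A2 could be tested, and of 9 endothelial markers VWF and ESAM; COL1A1 fell by 0.85 at 12 h and rose by 0.40 at 48 h, VWF rose by 0.52 at 24 h, and ESAM fell by 0.67 at 24 h and by 1.02 at 48 h. Median, mean and test differed in sign for the inhibitors, apoptosis, liver X receptor, immediate early and transforming growth factor beta lists at 12 h. They also differed for the inhibitors, apoptosis, metallothionein and leukocyte lists at 24 h, and for the pyruvate dehydrogenase, respiratory chain and mesenchymal lists at 48 h.

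Other splits of the same arrays were counted for each result. The 6 arrays of each pioglitazone or vehicle comparison make 10 splits, too few for a share under 0.05. The real split alone (1 of 10) reached 1028 genes at 12 h, 2725 at 24 h, 3469 at 48 h, 4275 for vehicle at 24 h and 2983 for vehicle at 48 h. The highest of the others called 0, 0, 2, 0 and 0. For the differences, treatment labels were exchanged within each time. Between 12 and 24 h, 7 of 100 splits gave at least 81 genes (highest other 3149), and between 24 and 48 h, 8 of 100 gave at least 398 (highest other 4607). Between 12 and 48 h, 3 of 100 gave at least 1063 (highest other 1682), a share under 0.05. These numbers include the real labels. Of the 6 splits besides the real one that reached 81 genes, 5 exchanged all 6 arrays of 1 time, and of the 7 that reached 398, 3 did, the highest of each among them. The other 4 of those 7 exchanged 4 of the 6 arrays of 1 time. Of the others that reached 1063, 1 exchanged all 6 arrays at 48 h and 1 exchanged 4 at 12 h. Exchanging all arrays of a time adds the effects of the times in place of subtracting them, and exchanging 4 inverts part of an effect. Splits of this kind are no null for a difference of effects. For the counts of 81, 398 and 1063 they cannot say whether chance gives as many. For the gene lists 1 of 100 splits, the real one, reached 54 calls (highest other 47), a share under 0.05. A split that leaves or inverts the labels of a time can keep the calls of that time, so this share does not bear on single lists.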
